A study of Mus musculus with 73 samples.

How the data were processed

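The series measured gene expression in microglia, the resident immune cells of the brain, by RNA sequencing. Per the labels, cells positive for CD11b and CD45 were isolated from mouse brains by fluorescence-activated cell sorting. The mice were wild type (WT), 5xFAD, a transgenic amyloid model of Alzheimer's disease that carries mutant human transgenes, or 5xFAD lacking CD33, TREM2 or both. Stranded mRNA libraries were made with the Illumina TruSeq kit. There were 73 libraries in 10 groups at 4 or 8 months of age, grouped by the genotype and age that the labels give, with no sample left out.

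Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with STAR and counted per gene with HTSeq. The submitters also name edgeR, with no role given. Their versions, the annotation release, the filters and the strand setting of the count are not given in the sources used here. The deposited values are RPKM, in 3 separate tables made by the authors, for all groups at 4 months, for CD33 knockout and 5xFAD at 8 months, and for TREM2 knockout, 5xFAD and WT at 8 months. Each table listed 39179 genes, of which 37693 IDs were in GENCODE mouse release M21. Positions on GRCm38 were taken from that release, which may differ from the authors' annotation, and 433 listed genes shared a symbol with another ID.

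In each library, RPKM multiplied by gene length was a whole multiple of a single step, so read numbers could be worked out. With a tolerance of 0.05 reads, 100% of the values were whole in every library. In units of 1e6 reads, the recovered totals ran from 21.19 to 79.65 with a median of 35.48. The values also showed that the authors' library sizes had been multiplied by a factor per library, from 0.8435 to 1.096. Over 279 pairs of libraries within groups, the lowest chi-square per degree of freedom was 4.975, so the spread between libraries exceeded counting error in each pair.

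Tests were run with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a two-sided moderated test (trended and robust) and Benjamini-Hochberg adjustment over the genes tested. Genes with RPKM of at least 1 in as many libraries as the smallest group of the table were tested, and an adjusted p under 0.05 was a call. All groups of a table entered 1 fit and shared its estimate of spread; no test crossed the tables. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of genes with low values. The ± after a log2 change is a standard error, and after a mean RPKM a standard deviation (SD). The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Library titles carry animal numbers, but nothing states that each library is a separate animal. The p-values therefore measure the spread between these libraries. Among the 5xFAD;TREM2-/- libraries at 8 months, the number of replicate 5 recurs in another title, which also carries a further number. Whether these libraries share an animal is not stated, so they may not be independent in the comparisons of that group.

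The 41 fixed lists held 487 genes. They covered microglial states, immune, lipid and metabolic programmes, and markers of other cell types, some of which a CD11b and CD45 gate can hold. Disease-associated microglia (DAM) genes were taken as 2 lists, with stage 2 the genes described as needing TREM2. Lists with at least 5 tested members were tested with camera in limma, which asks whether members rank apart from the other genes, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation stands beside it. Some lists hold markers that microglia also express or that another list holds.

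The named genes were Cd33 and Trem2 throughout, and, among calls with an ordinary symbol and a mean RPKM of at least 2 in either group, the 10 largest increases and the 10 largest decreases. Up to 4 members per described list with the smallest p were added. Where fewer than 5 genes passed, the 5 smallest p were named. App and Thy1, mouse genes related to a transgene and its promoter, were named for the model; Thy1 did not pass the filter. Some genes that this rule names are not reported here. A gene counted near a target if it lay within 10 Mb of it.

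The fit was tested on simulated data, drawn for the real genes from the means and library sizes of the real samples, with 200 changed genes per comparison. Of genes changed by a log2 of 1, it found 71% for the test of non-additivity and 73% for the double knockout against TREM2 knockout. Of those changed by 0.5 it found 20% and 38% there. In the other 9 comparisons it found 82 to 95% and 42 to 74%. Between 3 and 10 unchanged genes were called per comparison. Each gene was drawn on its own, with no batch or cell content shared over genes. These rates therefore do not cover false calls from libraries that deviate together.

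Comparisons that share 5xFAD libraries share their chance values. Correlations between their fold changes are therefore given with the median and range of 20 simulations of unchanged groups, and of 20 random splits of the 5xFAD libraries, in which each comparison received its own part. They are across genes, which are not independent replicates.

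The alternatives planned were pseudocounts of 0.1 and 1, no filter, a stricter filter (RPKM of at least 5), median-ratio scaling, the replicate number as a block, the batch number at the start of the titles as a term (the title batch), a Y-linked covariate, array weights, only the groups compared in the fit, and leaving out each library. Chosen after seeing the data were voom in limma on the recovered reads, a covariate of endothelial markers, leaving out genes within 10 Mb of the targets, and leaving out libraries with both Xist and Y-linked reads (each above 10% of its highest value in the table), a high mitochondrial share, or a title with 2 animal numbers. Figures were drawn with matplotlib 3.10.9.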

Results

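Gene expression was profiled by RNA sequencing in microglia sorted from mouse brain. 5xFAD mice, a transgenic amyloid model, were studied with both receptors intact or lacking CD33, a sialic acid-binding inhibitory receptor, TREM2, a lipid-sensing activating receptor, or both. At 4 months there were 7 WT, 9 5xFAD, 4 5xFAD;CD33-/-, 4 5xFAD;TREM2-/- and 2 double knockout libraries. At 8 months 1 table held 11 5xFAD and 12 5xFAD;CD33-/- libraries, and another held 6 WT, 10 5xFAD and 8 5xFAD;TREM2-/- libraries. In units of 1e6, recovered reads per library ran from 28.94 to 79.65 at 4 months, from 26.75 to 42.79 in the CD33 table and from 21.19 to 51.03 in the TREM2 table.

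The targeted genes were examined first. Cd33 (ENSMUSG00000004609, chromosome 7, 43524216 to 43544428 on GRCm38) lay between 0.0526 and 0.205 RPKM in the 4 5xFAD;CD33-/- libraries at 4 months, against 135.8 ± 12 (n = 9) in 5xFAD. At 8 months it was 0.605 or lower in 11 of the 12 5xFAD;CD33-/- libraries, against 123.5 ± 18.1 (n = 11) in 5xFAD. The library labelled 5xFAD;CD33-/- replicate 7 at 8 months held 19.1 RPKM, which goes against its label. Of the double knockouts, the library labelled double knockout replicate 1 held 14.02 RPKM and replicate 2 had no Cd33 read, which allows up to 0.0242 RPKM (3 reads, counting error only). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) fell to 32.3 ± 3.03 (n = 4) in 5xFAD;TREM2-/- at 4 months, against 740.3 ± 90.4 in 5xFAD. It was 30.0 ± 4.53 (n = 2) in the double knockouts, and 18.1 ± 2.86 (n = 8) in 5xFAD;TREM2-/- at 8 months against 808 ± 104 (n = 10). Loss of either receptor left the other transcribed: Cd33 was 159.2 ± 20.5 in 5xFAD;TREM2-/- at 4 months, and Trem2 was 762.6 ± 62.1 in 5xFAD;CD33-/- at 4 months and 816.1 ± 149 at 8 months.

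**Figure D1:**
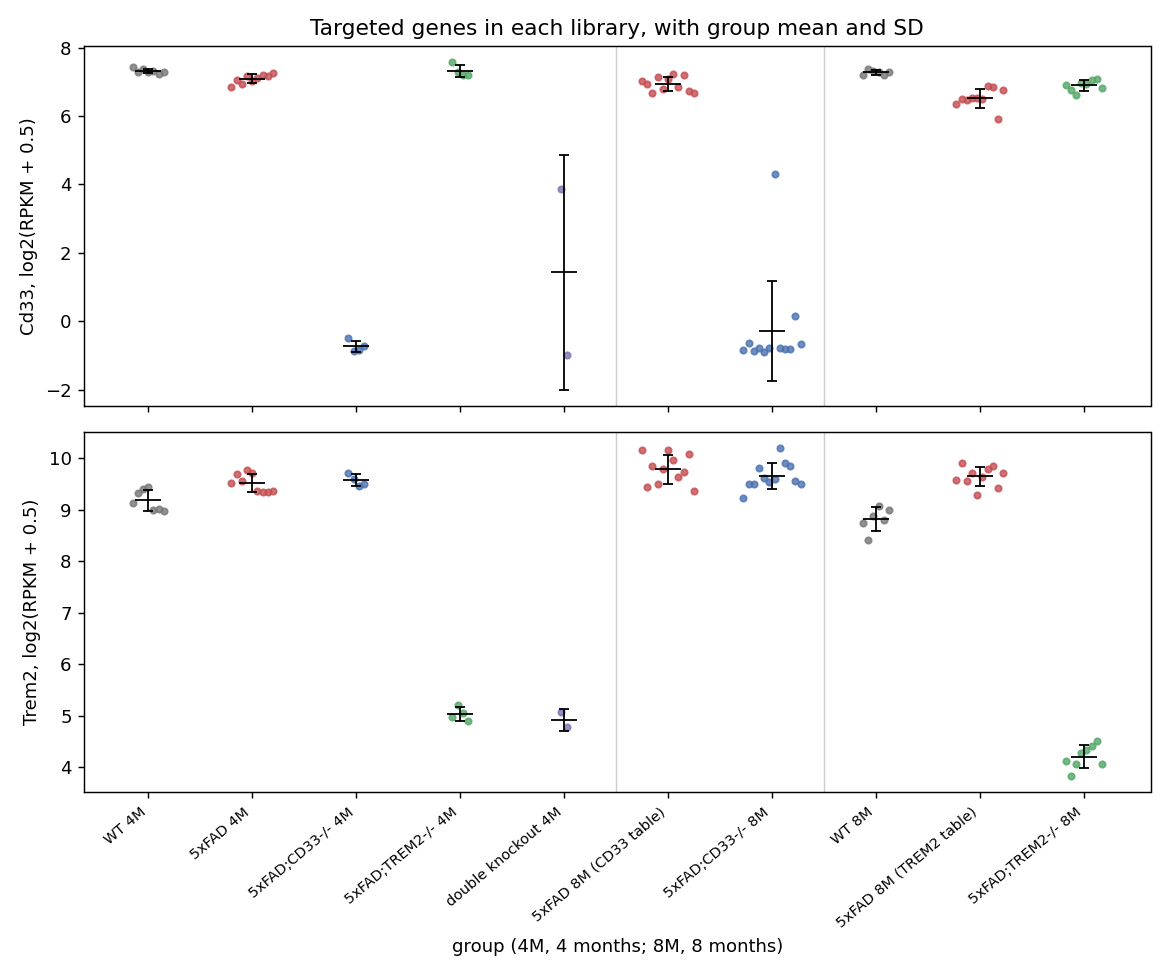
Cd33 (top) and Trem2 (bottom) in each library as log2(RPKM + 0.5), with group mean and SD, for the 10 groups (4M, 4 months; 8M, 8 months; vertical lines part the 3 tables). The library labelled 5xFAD;CD33-/- replicate 7 at 8 months and the library labelled double knockout replicate 1 lie above the other CD33 knockout libraries, at 19.1 and 14.02 RPKM.

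5xFAD was set against WT at 4 months to ask what the amyloid model changes in young adult microglia. Microglia of 5xFAD mice carried a DAM profile, headed by Cst7, Lpl, Axl and Clec7a. The interferon-response gene Ifi27l2a and the cell-cycle gene Mki67 rose with it, and the homeostatic marker Tmem119 fell. In limma 2181 of 13024 genes passed, 1166 higher and 1015 lower, with 151 higher and 5 lower by at least 2-fold. With the title batch as a term 2036 passed, and with a covariate of endothelial markers 1367. Cst7, which encodes a cysteine protease inhibitor, rose from 8.35 ± 0.913 RPKM in WT to 523.5 ± 202 (log2 change 5.79 ± 0.238, adjusted p = 2.31e-14, 9 of 9 libraries). Lpl, a lipoprotein lipase, rose by 3.89 ± 0.152 (adjusted p = 1.2e-14), the phagocytic receptor Axl by 3.66 ± 0.239 (adjusted p = 1.9e-10) and the β-glucan receptor Clec7a by 3.65 ± 0.174 (adjusted p = 3.41e-13). The lipid carrier Apoe rose from 287.9 ± 53.9 to 1450 ± 619 RPKM (2.22 ± 0.245, adjusted p = 6.9e-07), and the inflammatory cytokine Il1b from 24.5 ± 2.8 to 114.6 ± 40.9 (2.12 ± 0.22, adjusted p = 2.48e-07). Each of these genes was higher in 9 of 9 libraries. Trem2 rose by 0.34 ± 0.0857 (adjusted p = 0.00643, 9 of 9 libraries).

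All 24 tested DAM stage 2 genes rose at 4 months, also when adjusted over the list alone (median log2 change 1.38, camera adjusted p = 3.43e-39, adjusted p = 0.0135 with an estimated correlation). DAM stage 1 genes rose in 9 of 9, the same count adjusted over the list alone (camera adjusted p = 3.17e-13, adjusted p = 0.0367 with an estimated correlation). All 24 interferon-response genes rose as well, also adjusted over the list alone (median 1.24, adjusted p = 7.98e-29, adjusted p = 0.0367 with an estimated correlation). Among them Ifi27l2a rose by 2.68 ± 0.268 (adjusted p = 1.52e-07) and the chemokine gene Cxcl10, of the chemokine list, by 1.42 ± 0.205 (adjusted p = 2.78e-05). Of 18 proliferation genes 15 rose (16 adjusted over the list alone, adjusted p = 1.05e-19, adjusted p = 0.000354 with an estimated correlation). Mki67 rose from 0.533 ± 0.101 to 1.93 ± 0.315 RPKM (1.23 ± 0.0874, adjusted p = 4.96e-10). Of 17 cholesterol synthesis and uptake genes 11 rose (12 adjusted over the list alone, adjusted p = 1.05e-08, adjusted p = 0.0135 with an estimated correlation). Of 20 homeostatic genes 15 fell (18 adjusted over the list alone, median -0.32, adjusted p = 3.82e-10), a call lost with the other correlation (adjusted p = 0.141 with an estimated correlation). Tmem119, a microglial membrane protein, fell from 1866 ± 209 to 1260 ± 175 RPKM (-0.57 ± 0.0876, adjusted p = 4.99e-05, 9 of 9). Lysosomal genes (17 of 24 higher; adjusted p = 9.41e-13, adjusted p = 0.114 with an estimated correlation) and MHC class I genes (7 of 10; adjusted p = 9.17e-07, adjusted p = 0.141 with an estimated correlation) rose too. Markers of other cells moved with these: 3 of 8 endothelial markers were higher (7 adjusted over the list alone, median 0.77, adjusted p = 0.0023, adjusted p = 0.373 with an estimated correlation). In all 20 of 31 lists passed, 16 upward, and 5 with an estimated correlation. App, which the human transgene resembles, did not pass (0.24 ± 0.0973, adjusted p = 0.093). Cd33 was below the WT mean in 9 of 9 libraries without passing (135.8 ± 12 against 158.6 ± 7.85, adjusted p = 0.711) in a fit whose shared spread holds the unequal double knockout libraries.

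At 8 months the same comparison asked what the model changes at a later stage of amyloid deposition. The DAM profile was present with Gpnmb, a lysosomal glycoprotein, among the largest increases. The homeostatic marker Tmem119 was lower, and Cd74 was higher. In limma 7428 of 12622 genes passed, 3573 higher and 3855 lower, 720 and 126 of them by at least 2-fold. With the title batch as a term 6684 passed. Cst7 rose from 10.6 ± 1.52 to 1348 ± 195 RPKM (log2 change 6.92 ± 0.145, adjusted p = 4.53e-21), Gpnmb from 0.183 ± 0.0412 to 55.8 ± 28.2 (6.20 ± 0.273, adjusted p = 6.51e-15) and Apoe from 369.1 ± 8.44 to 4682 ± 1220 (3.62 ± 0.183, adjusted p = 7.71e-14), each in 10 of 10 libraries. The heparan sulfate-degrading enzyme Hpse rose by 4.80 ± 0.221 (adjusted p = 1.68e-14), Il1b by 3.39 ± 0.182 (adjusted p = 2.78e-13) and Cd74, the MHC class II invariant chain, by 1.87 ± 0.234 (adjusted p = 4.62e-07). Tmem119 fell from 1583 ± 92.9 to 657.4 ± 152 RPKM (-1.30 ± 0.131, adjusted p = 1.62e-08), and the endocytosis and Alzheimer's risk gene Bin1 fell by 0.82 on the log2 scale (SE 0.0793, adjusted p = 8.9e-09), both in 10 of 10 libraries. Cd33 itself fell from 154.6 ± 6.91 to 92.9 ± 16.9 RPKM (-0.75 ± 0.103, adjusted p = 1.43e-06, 10 of 10) while Trem2 rose by 0.83 ± 0.107 (adjusted p = 6.4e-07). App was higher by 0.46 ± 0.113 (adjusted p = 0.0014, 9 of 10), a call that a covariate of endothelial markers ended and turned to -0.09.

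All 24 DAM stage 2 genes rose at 8 months, also adjusted over the list alone (median log2 change 2.01, adjusted p = 1.3e-23, adjusted p = 0.0459 with an estimated correlation), as did 15 of 18 cholesterol genes, likewise adjusted over the list alone (adjusted p = 1.17e-06, adjusted p = 0.0459 with an estimated correlation). Interferon-response genes rose in 24 of 24 (median 1.73, adjusted p = 3.18e-15, adjusted p = 0.176 with an estimated correlation). Homeostatic genes fell in 19 of 20 (20 adjusted over the list alone, median -0.80, adjusted p = 1.54e-08, adjusted p = 0.29 with an estimated correlation). MHC class II genes rose in 5 of 7 (adjusted p = 0.0294, adjusted p = 0.434 with an estimated correlation). Of 17 genes of TREM2 signalling 13 fell and 3 rose (adjusted p = 0.00131, adjusted p = 0.36 with an estimated correlation). Markers of vessels moved with these changes: 8 of 8 endothelial markers (adjusted p = 0.00137, adjusted p = 0.36 with an estimated correlation) and 6 of 6 mural cell markers (adjusted p = 0.00422, adjusted p = 0.354 with an estimated correlation) were higher in 5xFAD. Cldn5, an endothelial tight junction protein, rose from 99.6 ± 38.1 to 284.2 ± 108 RPKM (1.47 ± 0.256, adjusted p = 3.89e-05, 10 of 10). With a covariate of endothelial markers this call ended, and 4035 genes passed in place of 7428. Cldn5 is itself part of that covariate, so the end of its call is partly built in. The covariate was also higher in 5xFAD, so it can take up part of other differences from WT. In all 20 of 31 lists passed, 17 upward, and 2 with an estimated correlation. Across 12340 genes tested at both ages the fold changes of 5xFAD against WT correlated at r = 0.876. In all 1101 genes were called higher at both ages (317 for independent lists) and 941 lower at both (314).

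**Figure D2:**
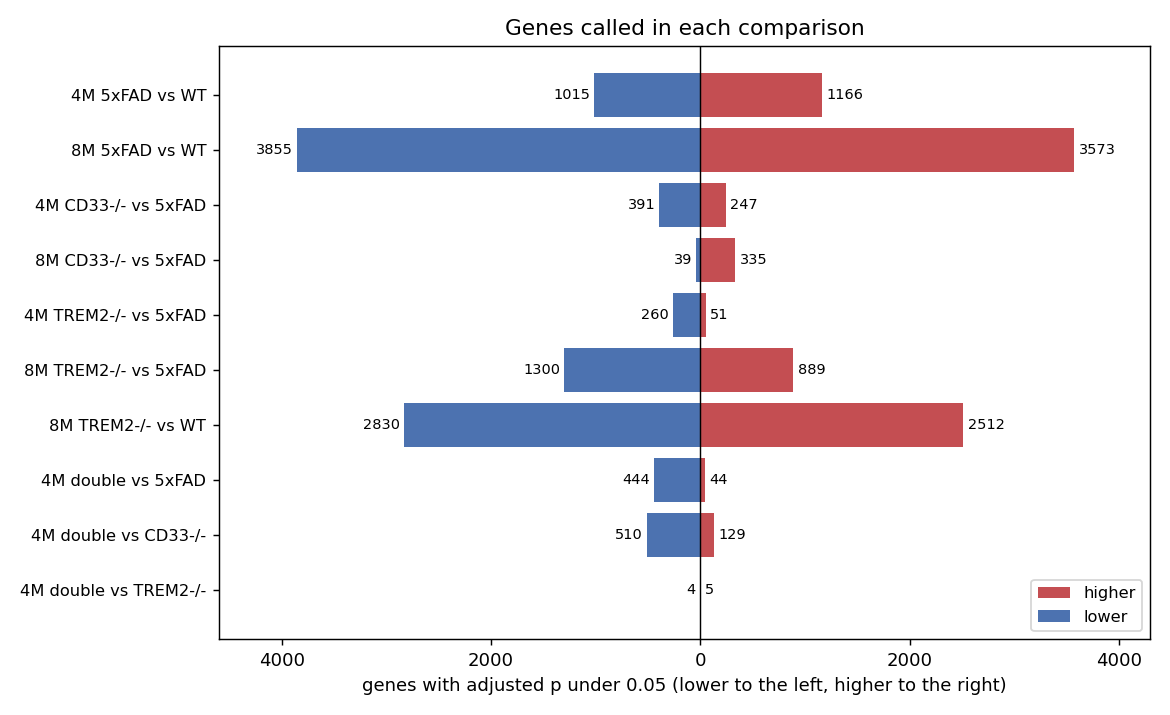
Number of genes with limma adjusted p under 0.05 in each comparison, higher to the right and lower to the left. The model at 8 months called 3573 higher and 3855 lower; the double knockout against 5xFAD;TREM2-/- called 5 and 4. With median-ratio scaling the 4-month CD33 knockout calls were 204 higher and 201 lower.

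CD33 knockout was compared with 5xFAD at 4 months to ask how loss of this inhibitory receptor changes microglia in the model. Of the called genes named here, Cd33, its chromosome 7 neighbours Klk8, Cd37, Ftl1 and Slc6a16, and Ftl2 kept their calls in every alternative fit. The cytokine genes Il1b and Il1rn passed upward, with calls lost without 5xFAD;CD33-/- replicate 2 or 3. In limma 638 genes passed, 247 higher and 391 lower (38.7% higher). Median-ratio scaling gave 405, with 204 higher and 201 lower (50.4%), no filter 216, with 113 higher and 103 lower (52.3%), and voom 1022, with 535 higher and 487 lower. The title batch as a term gave 1964, array weights 5084, only these groups in the fit 26, a covariate of endothelial markers 24 and leaving out the libraries with both Xist and Y-linked reads 22. The count rested on single libraries: it was 22 without 5xFAD;CD33-/- replicate 2, 24 without replicate 3, 1290 without replicate 1 and 2343 without replicate 4. Leaving out 5xFAD libraries gave 2298 without replicate 1, 106 without replicate 7, 418 without replicate 8, 203 without replicate 9, 156 without replicate 11 and 122 without replicate 13. Klk8, a kallikrein serine protease, fell from 68.0 ± 8.59 to 8.09 ± 1.6 RPKM (log2 change -3.005 ± 0.117, adjusted p = 2.1e-15) and Cd37, a tetraspanin, from 160.2 ± 10.7 to 80.0 ± 11.4 (-1.005 ± 0.0719, adjusted p = 9.85e-10), both in 4 of 4 libraries. Ftl2, annotated in M21 as a processed pseudogene of ferritin light chain, rose from 0.0367 ± 0.0403 to 30.0 ± 6.62 (5.81 ± 0.121, adjusted p = 1.26e-21) while its parent Ftl1 fell from 226.7 ± 25.4 to 108.5 ± 21 (-1.07 ± 0.133, adjusted p = 2.64e-05). Reads can be shared between such copies, so both values are uncertain. Of 132 tested genes within 10 Mb of Cd33, 25 were called (18.9%), against 4.75% elsewhere (Fisher's exact p = 4.52e-09).

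Il1b rose from 114.6 ± 40.9 to 262.7 ± 102 RPKM in 5xFAD;CD33-/- at 4 months (log2 change 1.17 ± 0.262, adjusted p = 0.0257, 4 of 4 libraries), the interleukin-1 antagonist Il1rn by 1.16 ± 0.236 (adjusted p = 0.0169), the chemokine gene Cxcl1 by 1.53 ± 0.278 (adjusted p = 0.00618) and the myelin gene Mobp by 1.13 ± 0.207 (adjusted p = 0.00618). None of these 4 calls held without 5xFAD;CD33-/- replicate 2 (log2 changes of Il1b 1.02, Il1rn 1.03, Cxcl1 1.38 and Mobp 0.94) or without replicate 3 (1.15, 1.05, 1.29 and 0.96). All 4 were also lost with a covariate of endothelial markers, with only these groups in the fit and without the libraries with both Xist and Y-linked reads. Of 24 DAM stage 2 genes 1 was called higher (3 adjusted over the list alone, median 0.28), and the list ranked above other genes (camera adjusted p = 2.94e-06, adjusted p = 0.608 with an estimated correlation). DAM stage 1 genes had 0 of 9 called (2 adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.608 with an estimated correlation). Homeostatic genes ranked lower with 1 of 20 called (4 adjusted over the list alone, adjusted p = 0.00105, adjusted p = 0.618 with an estimated correlation). Oligodendrocyte markers were higher in 5 of 8 (8 adjusted over the list alone, median 0.70, adjusted p = 6.01e-07, adjusted p = 0.596 with an estimated correlation), endothelial markers in 1 of 8 (8 adjusted over the list alone, median 0.98, adjusted p = 2.29e-05, adjusted p = 0.6 with an estimated correlation), and erythrocyte markers lower in 1 of 5 (5 adjusted over the list alone, adjusted p = 0.00262, adjusted p = 0.6 with an estimated correlation). In all 13 of 31 lists passed, 9 upward, and 0 with an estimated correlation. Trem2 did not pass (0.05 ± 0.102, adjusted p = 0.79).

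The 8-month comparison of CD33 knockout with 5xFAD addressed the same question with more libraries. Genes beside Cd33 changed again, Klk8, Cd37 and Ftl1 lower and Slc6a16 higher, with Ftl2 higher. Most of the calls were increases, led by endothelial genes such as Ly6c1, Cdh5 and Esam. No DAM stage 2 gene was called. In limma 374 of 11345 genes passed, 335 higher and 39 lower (89.6% higher). The stricter filter gave 145 and the title batch as a term 423, with 293 higher and 130 lower (69.3%). Leaving out single 5xFAD libraries gave 249 without replicate 1, 215 without replicate 4, 188 without replicate 5, 196 without replicate 6, 194 without replicate 7 and 236 without replicate 10. Leaving out single 5xFAD;CD33-/- libraries gave 207 without replicate 3, 561 without replicate 4, 212 without replicate 5, 246 without replicate 6, 207 without replicate 7 (the library labelled 5xFAD;CD33-/- that held Cd33) and 243 without replicate 11. Klk8 fell from 42.2 ± 7.46 to 10.9 ± 3.65 RPKM (-1.95 ± 0.138, adjusted p = 1.97e-09). Ftl2 rose by 5.09 ± 0.302 (adjusted p = 6.64e-11) and Ftl1 fell from 219.3 ± 77.7 to 38.2 ± 15.3 (-2.52 ± 0.203, adjusted p = 1.32e-08), with the same uncertainty between copies. Of 112 tested genes within 10 Mb of Cd33, 24 were called (21.4%), against 3.11% elsewhere (Fisher's exact p = 1.49e-13).

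All 8 endothelial markers were higher in 5xFAD;CD33-/- at 8 months, also adjusted over the list alone (median log2 change 1.04, adjusted p = 2.84e-12, adjusted p = 0.208 with an estimated correlation). Ly6c1, a surface protein of brain endothelium, rose from 50.6 ± 18.9 to 124.1 ± 54.9 RPKM (1.27 ± 0.249, adjusted p = 0.0109, 11 of 12 libraries), the vascular cadherin gene Cdh5 by 0.95 ± 0.209 (adjusted p = 0.0143, 12 of 12) and the endothelial adhesion molecule gene Esam by 1.16 ± 0.268 (adjusted p = 0.0194, 11 of 12). With a covariate of endothelial markers these 3 calls ended, Esam at -0.06, and 13 genes passed in place of 374. The 3 genes are themselves part of that covariate, so the end of their calls is partly built in. The covariate was also higher in the knockout, so it can take up part of other differences between the genotypes. Interferon-response genes ranked higher with 0 of 24 called (6 adjusted over the list alone, median 0.24, adjusted p = 1.57e-08, adjusted p = 0.936 with an estimated correlation), and the smallest adjusted p among the members belonged to Ifit1 at 0.0523 (0.50 ± 0.143). Homeostatic genes ranked lower with 0 of 20 called, also over the list alone (median -0.16, adjusted p = 0.0057, adjusted p = 0.936 with an estimated correlation), and so did neutrophil markers with 0 of 10 (adjusted p = 0.0403, adjusted p = 0.936 with an estimated correlation). The DAM stage 2 list did not pass (0 of 24 called, also over the list alone, median -0.08, adjusted p = 0.131), nor did Trem2 (-0.14 ± 0.111, adjusted p = 0.585). In all 4 of 30 lists passed, 2 upward, and 0 with an estimated correlation. Fold changes of CD33 knockout at 4 and 8 months, from tables with no shared libraries, correlated at r = 0.695 across 11247 genes (0.665 without genes within 10 Mb of the targets). In all 66 genes were called higher at both ages (5.6 for independent lists) and 18 lower (1.27). Endothelial markers ranked higher in the knockout at both ages, and these values were not computed with the endothelial covariate. They therefore do not tell a shared endothelial signal from other effects of CD33 loss.

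TREM2 knockout was compared with 5xFAD at 4 months to ask which part of the microglial response needs TREM2. Axl, Cst7, Lpl and Itgax, which the model raised, were lower, and so were Il1b and Ch25h. Genes beside Trem2 on chromosome 17 changed in both directions. In limma 311 genes passed, 51 higher and 260 lower. The count was 178 with the title batch as a term, 148 with only these groups in the fit, 499 with array weights, 468 with a covariate of endothelial markers and 184 without the libraries with both Xist and Y-linked reads. It was 157 without 5xFAD;TREM2-/- replicate 1 and 207 without replicate 9. Cst7 fell from 523.5 ± 202 to 81.4 ± 37.7 RPKM (-2.70 ± 0.284, adjusted p = 1.6e-06), Lpl from 47.8 ± 14.9 to 9.11 ± 1.55 (-2.28 ± 0.181, adjusted p = 1.23e-08), Axl from 58.7 ± 26.4 to 8.08 ± 2.66 (-2.70 ± 0.285, adjusted p = 1.6e-06) and the integrin gene Itgax from 48.9 ± 20.5 to 10.4 ± 3.58 (-2.12 ± 0.272, adjusted p = 3.01e-05). Il1b fell by 1.48 on the log2 scale (SE 0.262, adjusted p = 0.00132) and Ch25h, which makes 25-hydroxycholesterol, by 2.00 (SE 0.31, adjusted p = 0.000295), each in 4 of 4 libraries. Apoe did not pass (-0.96 ± 0.292, adjusted p = 0.0944), nor did Cd33 (0.23 ± 0.432, adjusted p = 0.945). Of 24 DAM stage 2 genes 15 fell (22 adjusted over the list alone, median -0.76, adjusted p = 1.9e-41, adjusted p = 0.0152 with an estimated correlation). Of 17 cholesterol genes 6 fell (10 adjusted over the list alone, adjusted p = 6.55e-14, adjusted p = 0.00257 with an estimated correlation), and 4 of 18 proliferation genes (8 adjusted over the list alone, adjusted p = 4.36e-07, adjusted p = 0.0416 with an estimated correlation). Interferon-response genes fell in 9 of 24 (18 adjusted over the list alone, adjusted p = 9.67e-22, adjusted p = 0.0618 with an estimated correlation) and DAM stage 1 genes in 4 of 9 (9 adjusted over the list alone, adjusted p = 3.89e-12, adjusted p = 0.0508 with an estimated correlation). Homeostatic genes ranked higher with 0 of 20 called (1 adjusted over the list alone, adjusted p = 4.67e-08, adjusted p = 0.199 with an estimated correlation). In all 18 of 31 lists passed, 16 downward, and 3 with an estimated correlation.

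Near Trem2 at 4 months, 17 of 143 tested genes within 10 Mb were called (11.9%), against 2.27% elsewhere (Fisher's exact p = 4.97e-08). The neighbouring receptor genes moved apart: Treml2 fell from 9.23 ± 1.74 to 2.33 ± 0.41 RPKM (-1.77 ± 0.114, adjusted p = 1.63e-10) and Treml4 rose from 0.271 ± 0.147 to 3.08 ± 0.424 (2.23 ± 0.165, adjusted p = 2.57e-09). Unc5cl, an adaptor gene, rose by 1.56 ± 0.0953 (adjusted p = 7.21e-11) and the nonclassical MHC gene H2-T24 by 0.96 ± 0.0856 (adjusted p = 7.79e-08). At 8 months 36 of 140 such genes were called (25.7%), against 17.2% elsewhere (Fisher's exact p = 0.0129), and Treml2 fell by 1.46 (SE 0.117, adjusted p = 1.48e-09) while Treml4 rose by 1.60 ± 0.117 (adjusted p = 3.2e-10).

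At 8 months TREM2 knockout was set against 5xFAD and against WT to ask what the response loses and what remains without TREM2. Against 5xFAD the DAM genes Gpnmb, Cst7, Lpl and Spp1 were among the largest decreases, and Cd74 and Srebf2 fell as well. Against WT Cst7, Gpnmb and Apoe were still higher. In limma 2189 genes passed against 5xFAD, 889 higher and 1300 lower (7 and 113 by at least 2-fold), and 2591 passed with the title batch as a term. Against WT 5342 passed, 2512 higher and 2830 lower, and 4732 with the title batch. Cst7 was 217 ± 61 RPKM in 5xFAD;TREM2-/-, 1348 ± 195 in 5xFAD (-2.67 ± 0.133, adjusted p = 4.22e-13) and 10.6 ± 1.52 in WT (4.25 ± 0.152, adjusted p = 5.89e-16). Gpnmb fell from 55.8 ± 28.2 to 5.95 ± 2.16 (-3.02 ± 0.251, adjusted p = 3.25e-09) and stayed above WT (3.18 ± 0.285, adjusted p = 2.37e-08). Apoe was 2719 ± 841, below 5xFAD (-0.81 ± 0.168, adjusted p = 0.00122) and above WT (2.81 ± 0.191, adjusted p = 1.79e-10). Cd74 fell by 1.61 against 5xFAD (SE 0.215, adjusted p = 7.13e-06) and did not pass against WT (0.26 ± 0.245, adjusted p = 0.412). Il1b fell from 411.1 ± 116 to 108.6 ± 36.1 (-1.94 ± 0.167, adjusted p = 5.87e-09). Stab1, a scavenger receptor, rose by 0.91 ± 0.0935 (adjusted p = 1.02e-07), and Cd33 rose from 92.9 ± 16.9 to 118.8 ± 12.5 (0.37 ± 0.0943, adjusted p = 0.00761), each in 8 of 8 libraries. Against WT Cd33 was lower (-0.39 ± 0.107, adjusted p = 0.00554, 8 of 8), a call lost with a covariate of endothelial markers (0.11).

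Against 5xFAD at 8 months, DAM stage 2 genes fell in 24 of 24, also adjusted over the list alone (median log2 change -1.30, adjusted p = 7.83e-37, adjusted p = 0.00612 with an estimated correlation), and cholesterol genes in 12 of 18 (14 adjusted over the list alone, adjusted p = 1.55e-15, adjusted p = 0.000567 with an estimated correlation). Srebf2, the regulator of the pathway, fell as well (log2 change -0.62 ± 0.0683, adjusted p = 4.23e-07). MHC class II genes fell in 6 of 7 (7 adjusted over the list alone, median -1.02, adjusted p = 7.5e-07, adjusted p = 0.125 with an estimated correlation), lysosomal genes in 16 of 25 (18 adjusted over the list alone, adjusted p = 4.95e-13, adjusted p = 0.16 with an estimated correlation) and interferon-response genes in 10 of 24 (11 adjusted over the list alone, adjusted p = 4.67e-05, adjusted p = 0.449 with an estimated correlation). Homeostatic genes rose in 4 of 20 (5 adjusted over the list alone, adjusted p = 0.00207, adjusted p = 0.576 with an estimated correlation), with Mef2a, a transcription factor, up by 0.27 ± 0.0616 (adjusted p = 0.00289). Oligodendrocyte markers moved with these, 3 of 8 higher (7 adjusted over the list alone, adjusted p = 0.000965, adjusted p = 0.393 with an estimated correlation). Against WT, DAM stage 2 genes were higher in 24 of 24 (median 0.93, adjusted p = 9.13e-18, adjusted p = 0.274 with an estimated correlation), interferon-response genes in 23 of 24 (24 adjusted over the list alone, adjusted p = 9.13e-18, adjusted p = 0.285 with an estimated correlation) and homeostatic genes lower in 17 of 20 (18 adjusted over the list alone, adjusted p = 7.18e-09, adjusted p = 0.344 with an estimated correlation). The chemokine receptor gene Cx3cr1 fell too (log2 change -0.81 ± 0.111, adjusted p = 6.55e-06), a call lost with a covariate of endothelial markers. Cholesterol genes did not pass against WT (3 of 18 higher and 1 lower; adjusted p = 0.574). Endothelial markers were higher than in WT in 8 of 8 (median 1.67, adjusted p = 7.17e-06, adjusted p = 0.344 with an estimated correlation), and with a covariate of endothelial markers 1026 genes passed against WT in place of 5342. In all 17 of 31 lists passed against 5xFAD, 13 downward, and 2 with an estimated correlation. Against WT 17 passed, 14 upward, and 0 with it. TREM2 knockout at 4 and 8 months, with no shared libraries, correlated at r = 0.669 across 12340 genes, and 243 genes were called lower at both ages (26.7 for independent lists).

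**Figure D3:**
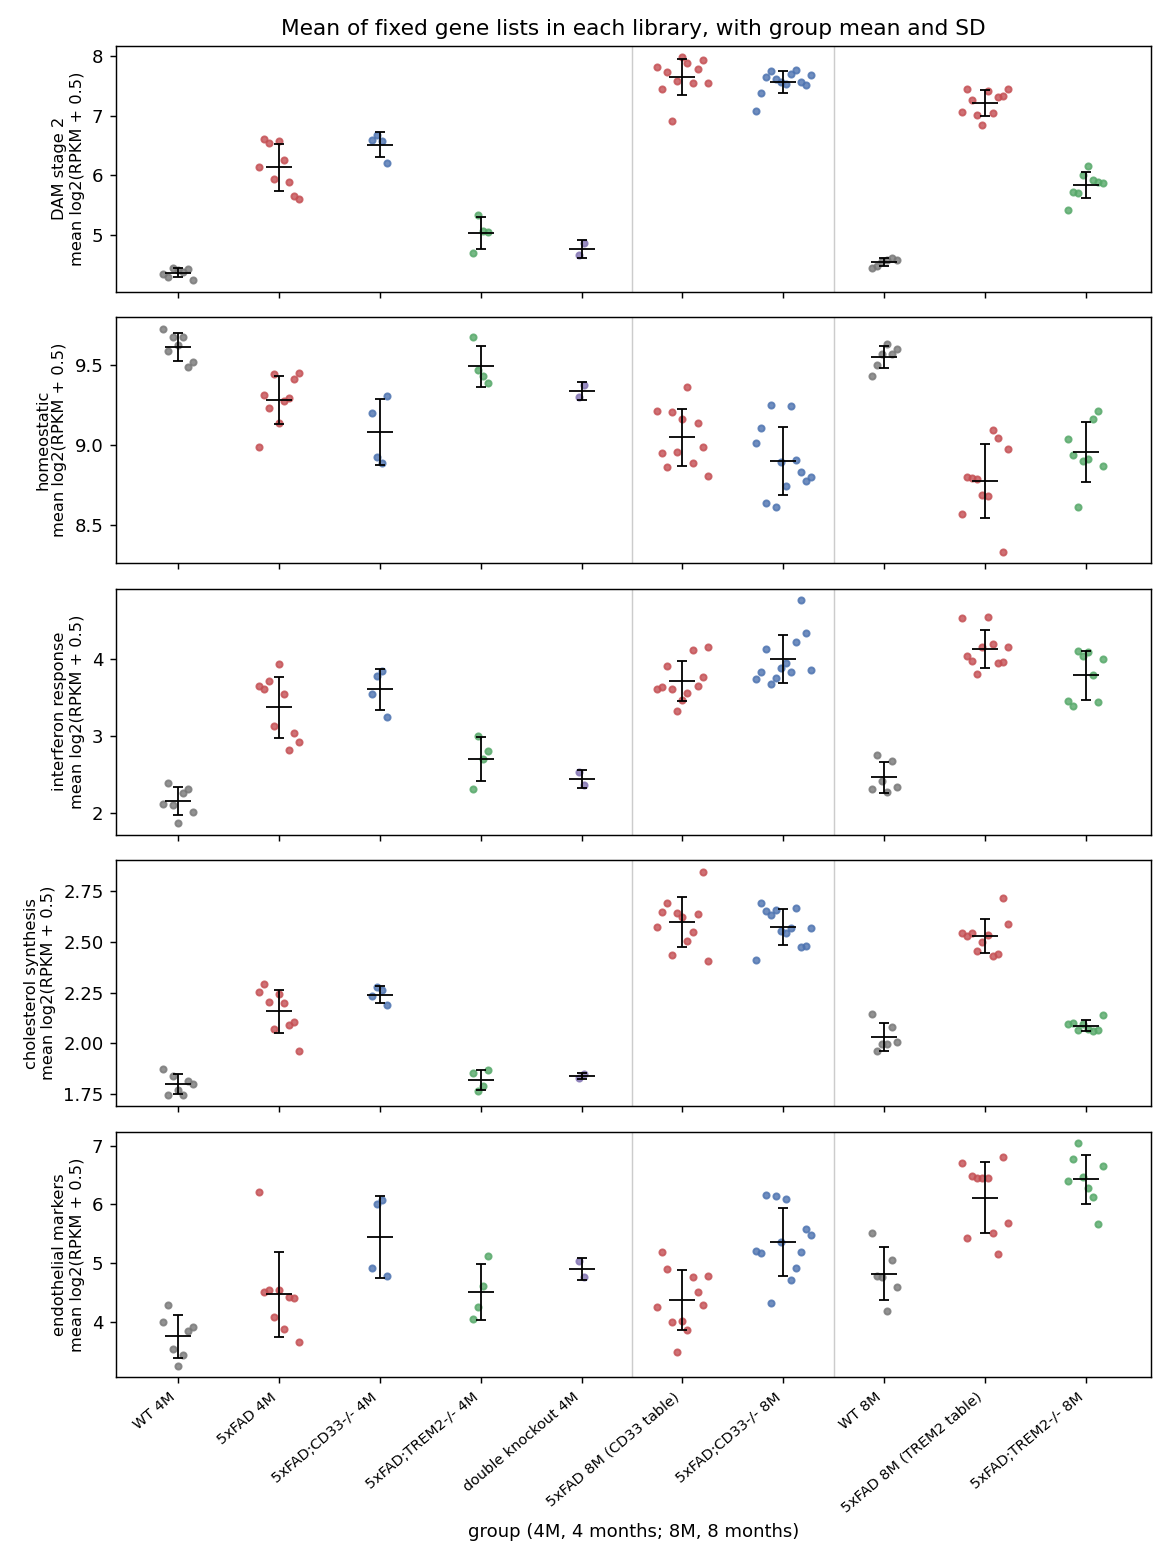
Mean log2(RPKM + 0.5) of 5 fixed gene lists in each library, with group mean and SD (4M, 4 months; 8M, 8 months; vertical lines part the 3 tables, which are not compared with each other). DAM stage 2, interferon and cholesterol means lie lower in 5xFAD;TREM2-/- than in 5xFAD, and endothelial markers lie higher in 5xFAD;CD33-/- than in 5xFAD at 8 months (5.36 against 4.37).

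The double knockout was compared with each single knockout and with 5xFAD at 4 months to ask whether loss of CD33 matters where TREM2 is missing. Against 5xFAD the DAM genes Cst7, Lpl and Axl were lower in the double knockouts. Against 5xFAD;CD33-/- Cst7, Itgax and Il1b were lower. Against 5xFAD;TREM2-/- only 9 genes were called, 6 of them Cd33 and genes within 10 Mb of it and 3 elsewhere or without a position. Only 2 double knockout libraries were present, and the library labelled double knockout replicate 1 held Cd33. Double knockout replicate 2 was the only library of its title batch. With the title batch as a term, the double knockout values here and below therefore rest on replicate 1 alone. Against 5xFAD 488 genes passed in limma, 44 higher and 444 lower. The count was 75 with the title batch as a term, 167 with only these groups in the fit, 142 without the libraries with both Xist and Y-linked reads, 181 without double knockout replicate 1 and 147 without replicate 2. Cst7 fell from 523.5 ± 202 to 45.2 ± 11.7 RPKM (-3.44 ± 0.369, adjusted p = 1.69e-06), Lpl by 3.18 (SE 0.236, adjusted p = 2.85e-09) and Axl by 3.20 (SE 0.371, adjusted p = 5.53e-06), each in 2 of 2 libraries. Of 24 DAM stage 2 genes 17 fell (22 adjusted over the list alone, adjusted p = 1.35e-31, adjusted p = 0.039 with an estimated correlation). Cholesterol genes fell in 5 of 17 (10 adjusted over the list alone, adjusted p = 1.93e-07, adjusted p = 0.039 with an estimated correlation) and interferon-response genes in 14 of 24 (20 adjusted over the list alone, adjusted p = 8.71e-18, adjusted p = 0.101 with an estimated correlation). In all 18 of 31 lists passed, 15 downward, and 3 with an estimated correlation.

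Against 5xFAD;CD33-/- 639 genes passed in the double knockout, 129 higher and 510 lower. The title batch as a term gave 189, only these groups in the fit 206, array weights 1635 and leaving out the libraries with both Xist and Y-linked reads 169. Leaving out double knockout replicates gave 332 without replicate 1 and 279 without replicate 2, and leaving out 5xFAD;CD33-/- libraries 401 without replicate 2, 382 without replicate 3 and 1224 without replicate 4. Cst7 fell from 809.3 ± 199 (n = 4) to 45.2 ± 11.7 RPKM (-4.13 ± 0.409, adjusted p = 9.38e-07), Itgax by 3.51 (SE 0.392, adjusted p = 5.7e-06) and Il1b from 262.7 ± 102 to 30.0 ± 8.73 (-3.03 ± 0.378, adjusted p = 1.97e-05). DAM stage 2 genes fell in 22 of 24 (24 adjusted over the list alone, median -1.58, adjusted p = 1.49e-36, adjusted p = 0.0266 with an estimated correlation), and interferon-response genes in 16 of 24 (24 adjusted over the list alone, adjusted p = 2.83e-20, adjusted p = 0.0814 with an estimated correlation). In all 18 of 31 lists passed, 17 downward, and 2 with an estimated correlation. Cd33 itself was called higher (2.16 ± 0.623, adjusted p = 0.0449, 1 of 2 libraries), a direction set by the library labelled double knockout replicate 1 (-0.27 without it). The call also ended without 5xFAD;CD33-/- replicate 1 (2.24), replicate 2 (2.12) or replicate 3 (2.13). It ended as well with no filter, a pseudocount of 0.1, voom (0.69), a covariate of endothelial markers, only these groups in the fit and without the libraries with both Xist and Y-linked reads (-0.31).

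Against 5xFAD;TREM2-/-, 9 genes passed in the double knockout, 5 higher and 4 lower. In all 5 passed with the title batch as a term, 5 with the stricter filter, 22 with no filter, 14 with array weights, 17 without double knockout replicate 1, 17 without the libraries with both Xist and Y-linked reads and 2 without genes within 10 Mb of the targets. Klk8 fell from 70.2 ± 6.25 to 10.4 ± 3.37 RPKM (-2.73 ± 0.168, adjusted p = 8.97e-11) and Cd33 fell by 5.88 (SE 0.623, adjusted p = 3.96e-06), a call lost with only these groups in the fit. Cd37 fell by 0.72 (SE 0.104, adjusted p = 0.000473), a call lost without double knockout replicate 1 (-0.58), with the title batch, with only these groups in the fit and without the libraries with both Xist and Y-linked reads. Ftl2 was 27.1 ± 9.25 RPKM against libraries all listed at 0, and the transporter gene Slc6a16 was called under both of its IDs. Predicted genes were called as well. Trem2 did not pass (-0.11 ± 0.147, adjusted p = 0.935), and no DAM stage 2 gene passed, also over the list alone, though the list ranked lower (median -0.23, adjusted p = 0.00392, adjusted p = 0.752 with an estimated correlation). Lpl was 4.67 ± 1.25 against 9.11 ± 1.55 without passing (-0.90 ± 0.261, adjusted p = 0.515). In all 13 of 31 lists passed, 9 downward, and 0 with an estimated correlation. The test of non-additivity of the knockouts called 0 genes in limma and 0 with voom, with 664 at an unadjusted p under 0.05 (690 with voom). In all 4 genes passed with no filter, 1 with the title batch, 1 without double knockout replicate 1 and 1 without replicate 2. Among the genes with the smallest p were S1pr2 (0.55 ± 0.147), Dph2 (0.52 ± 0.145), Sugt1 (-0.41 ± 0.113) and Srbd1 (-0.35 ± 0.0943), each with an adjusted p of 0.91. The DAM stage 2 list ranked lower in that test with 0 of 24 called (6 adjusted over the list alone, median -0.53, adjusted p = 1.96e-13, adjusted p = 0.566 with an estimated correlation), among 15 of 31 lists that passed, 14 of them downward, and 0 with an estimated correlation.

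The directions of model and knockout effects were then compared gene by gene. Of the 151 genes raised at least 2-fold by the model at 4 months, 150 were lower in 5xFAD;TREM2-/- than in 5xFAD (100 called), 149 were lower in the double knockout (98 called) and 13 in 5xFAD;CD33-/- (1 called lower, 6 called higher). With separate 5xFAD libraries for model and knockout, the median shares lower were 88.7% (range over the splits 55.3 to 98.6%), 90.4% (55 to 96.5%) and 13.1% (3.96 to 31.2%). At 8 months 406 of 720 such genes were lower in 5xFAD;TREM2-/- (284 called), with a median share of 58.8% in the splits (38.9 to 85.4%). Their median log2 change there ran from -0.456 to 0.207, so its direction depended on the split. The 720 genes include vessel genes such as Cldn5, and how many was not counted. The mean of endothelial markers was not lower in 5xFAD;TREM2-/- than in 5xFAD, while every tested DAM stage 2 gene was called lower. The share over the 720 genes therefore does not measure the DAM response alone. Of 126 genes lowered at least 2-fold by the model at 8 months, 3 were lower in 5xFAD;TREM2-/- and 71 were called higher. Their median log2 change was 0.422, with shared 5xFAD libraries and no split. The fold changes of the model and of TREM2 knockout at 4 months correlated at r = -0.68 across 13024 genes, against a median of -0.443 in simulations of unchanged groups (range -0.775 to 0.0275) and -0.548 with split 5xFAD libraries (-0.611 to -0.166). The value of r lay within the simulated range, while the covariance of -0.0466 lay outside it (-0.0282 to 0.000961). In all 248 genes were called higher in the model and lower in the knockout (23.3 for independent lists). At 8 months the same pair gave r = -0.586, also within the simulated range (median -0.441, -0.77 to 0.0979; split -0.52), and a covariance of -0.0866 outside it (-0.0197 to 0.00136), with 1115 such genes (368 for independent lists). For the model and CD33 knockout at 4 months r was 0.378, outside the simulated range (median -0.433, -0.782 to 0.0897). It was 0.409 with split 5xFAD libraries. The covariance of 0.0361 lay outside its range too (-0.0274 to 0.0019). Here 34 genes were called higher in both (22.1 for independent lists) and 103 lower in both (30.5). Endothelial markers ranked higher in both comparisons, and no value here was computed with the endothelial covariate. These values and the 13 of 151 genes above therefore do not tell a shared endothelial signal from other shared effects. The calls of this knockout also rested on single libraries, with 22 in place of 638 without 5xFAD;CD33-/- replicate 2. TREM2 knockout and double knockout correlated at r = 0.612, within the simulated range (median 0.318, -0.264 to 0.811; split 0.412), with a covariance of 0.0474 outside it (-0.00628 to 0.0338) and 207 genes called lower in both (8.86 for independent lists). CD33 knockout and TREM2 knockout gave r = -0.0473 at 4 months (split -0.155) and a covariance of -0.00338, both within the simulated ranges (-0.154 to 0.647 and -0.00503 to 0.0202), with 11 genes called higher in the first and lower in the second (4.93 for independent lists), and r = 0.137 at 8 months, where no libraries were shared.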

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

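The tests of explanations in this part were chosen after the results were seen: the position of calls around the targeted genes, the summed ferritin reads, the endothelial covariate, the gap between cell markers, the libraries with a high mitochondrial share, and the position of the library with Cd33 reads between the genotypes. The search for samples far from the others and for opposite changes at the 2 ages was planned.

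Of 77 combinations of a group and a measure searched for a sample far from the others, 4 held such a sample, and chance alone gives about 1 in 20. The double knockouts and the groups of the CD33 table were not searched, because of their numbers of libraries. The search therefore could not flag the knockout libraries that held Cd33. The endothelial mean of 5xFAD replicate 1 at 4 months was 6.21 on the log2 scale, against 3.66 to 4.55 in the other 8 libraries. The mitochondrial mRNA share of 5xFAD;TREM2-/- replicate 1 at 4 months was 1.04%, against 0.605 to 0.638% in the other 3. In WT replicate 1 at 4 months that share was 1.1%, against 0.509 to 0.758% in the other 6. These 3 libraries carried the same title batch, which no other library had, so a cause in that batch stays open for all 3 values. The high mitochondrial share was not common to the batch, since 5xFAD replicate 1 held 0.642%, where its group ran from 0.6195 to 0.9518%. 5xFAD replicate 4 at 4 months held 79.65 reads in units of 1e6, against 28.94 to 49.7 in the others. Of 285 genes compared between ages, Mog, a myelin gene, moved one way in every 5xFAD;TREM2-/- library at 4 months (log2 change -0.30 ± 0.227 against 5xFAD) and the other way in every such library at 8 months (0.79 ± 0.224), a difference that was not tested.

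The CD33 knockout comparisons called genes around Cd33 more often than elsewhere, at least 3.99 times as often within 10 Mb at both ages. An effect on the closest neighbours alone is argued against, since between 1 and 10 Mb from the target the share called was up to 6.7 times that elsewhere. A mere transfer of reads between Ftl1 and Ftl2 is argued against by their summed share of the reads, which changed by -2.18 ± 0.182 on the log2 scale at 8 months, although other ferritin copies were not summed. A chromosome segment of another strain carried along with the targeted allele is a candidate explanation that stays open, since calls lay both within 1 Mb of Cd33 and between 1 and 10 Mb from it at both ages, while the labels give C57BL/6 for the strain. Around Trem2 the lower ratio of the 2 ages was 1.49. Within 1 Mb of Trem2, 10 of 23 tested genes were called at 4 months and 10 of 21 at 8 months. Between 1 and 10 Mb it was 5.83% against 2.27% elsewhere at 4 months (Fisher's exact p = 0.0212). At 8 months it was 21.8% against 17.2% (p = 0.181, same test). A carried segment, an effect on the closest neighbours and an effect of the lost receptor cannot be told apart there, because no ratio in these comparisons decides between them.

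Endothelial genes were higher in 5xFAD;CD33-/- than in 5xFAD at 8 months, by a mean of 0.995 ± 0.227 over 8 of 8 markers. The 6 libraries with a high mitochondrial share are argued against as the source, since the change was 1.04 ± 0.265 without them. A lower share of microglia that raises all other cells evenly is argued against by the gap of 0.865 ± 0.169 between endothelial and mural changes. That gap was the widest, in standard errors, over the lists compared. These were astrocyte (0.355 ± 0.156), oligodendrocyte (0.254 ± 0.208), mural (0.13 ± 0.219) and neutrophil markers (-0.478 ± 0.304). A lower share with an uneven rise cannot be told apart from more endothelial RNA by these values. Of 327 upward calls outside the surroundings of Cd33, 1 remained with the endothelial mean as a covariate, a result that is partly built into the covariate where markers and calls are the same genes. More endothelial RNA carried over into the knockout libraries may therefore account for these calls, with Ly6c1 at 124.1 and Ly6a at 171.8 RPKM in the knockout, although a CD11b and CD45 gate would remove endothelial cells. A change of the vessels or of their attachment to microglia in mice lacking CD33 was not tested and stays open.

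The library labelled 5xFAD;CD33-/- replicate 7 at 8 months held Cd33 at 15.5% of the 5xFAD mean. A wrong label of the whole library is argued against, since Cd33 would then lie near that mean. Over 7 other called genes near Cd33, the library lay at a median of 27.3% of the way from the other knockout libraries to 5xFAD, where the others lay at 8.99% or lower. RNA of a Cd33-carrying animal mixed into the library may explain both values. A biological explanation was not tested.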

How the results depend on the processing

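The fits with voom, an endothelial covariate, no genes near the targets, and without libraries with both Xist and Y-linked reads, with a high mitochondrial share or with 2 animal numbers in the title were chosen after seeing the data; the other alternatives were planned. Over 270 combinations of a gene named in the text and a comparison, 7453 values were computed. Of these 7230 kept their side of the threshold and, where called, their direction. In all 134 lost a call, 83 gained a call and 6 turned direction with a call in either fit. Values called in neither fit counted as kept even where their direction turned. Median-ratio scaling and a pseudocount of 1 kept 270 of 270. For every change of a count below, the cause was not tested unless given.

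The replicate numbers did not pair the libraries at 4 months or in the CD33 table. Same-numbered libraries of different groups had a median correlation of 0.00645 at 4 months, -0.14 in the CD33 table and 0.145 in the TREM2 table. It was over 0.1 in 5 of 22, 4 of 11 and 8 of 15 pairs. Pairs with other numbers had medians of 0.00155, -0.0546 and -0.013, so a pairing stays open in the TREM2 table. Libraries of different groups with the same title batch deviated together with a median correlation of 0.0706, 0.344 and 0.19 in these tables, over 0.1 in 11 of 25, 13 of 18 and 16 of 26 pairs, against -0.00652, -0.0749 and -0.0199 for other pairs. With the replicate block the count of calls was 1306 for the model at 4 months (2181 without it), 19 for CD33 knockout at 4 months, 320 for the double knockout against 5xFAD, 379 for it against CD33 knockout, 19 for CD33 knockout at 8 months and 1223 for TREM2 knockout at 8 months. The calls of Trem2 in the model at 4 months and of Ly6c1, Cdh5 and Esam in CD33 knockout at 8 months were among 22 calls of named genes lost with the block. So were those of Il1b, Il1rn, Cxcl1 and Mobp in CD33 knockout at 4 months, and of Cd37 in the double knockout against TREM2 knockout. Cd33 lost its call with the block in the double knockout against CD33 knockout and in TREM2 knockout against WT at 8 months.

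For CD33 knockout at 4 months (638 calls), the count was 216 with no filter, 405 with median-ratio scaling, 1964 with the title batch, 5084 with array weights, 26 with only its groups in the fit, 1022 with voom, 24 with the endothelial covariate and 22 without the libraries with both Xist and Y-linked reads. Array weights let the data weigh libraries of the group, and leaving out libraries leaves fewer samples. For TREM2 knockout at 4 months (311) it was 178 with the title batch, 499 with array weights, 148 with only its groups, 468 with the endothelial covariate and 184 without the libraries with both Xist and Y-linked reads. For the double knockout against 5xFAD (488) these were 75 with the title batch, 167 with only its groups and 142 without those libraries. Against CD33 knockout (639) they were 189, 206 and 169, and 1635 with array weights. Against TREM2 knockout (9) the count was 22 with no filter, 5 with the stricter filter, 5 with the title batch, 14 with array weights, 17 without those libraries and 2 without genes within 10 Mb of the targets, where fewer genes were tested. The test of non-additivity called 4 with no filter and 1 with the title batch. The model at 4 months called 1367 with the endothelial covariate. At 8 months CD33 knockout (374) called 145 with the stricter filter and 13 with the endothelial covariate, the model 4035 and TREM2 knockout against WT 1026 with that covariate.

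Leaving out each library in turn, the count ranged from 1750 to 2634 for the model at 4 months. For CD33 knockout at 4 months it ranged from 22 (without 5xFAD;CD33-/- replicate 2) to 2343 (without replicate 4), and for TREM2 knockout from 157 (without 5xFAD;TREM2-/- replicate 1) to 433. For the double knockout it ranged from 147 (without its replicate 2) to 533 against 5xFAD, from 8 to 17 (without its replicate 1) against TREM2 knockout, and from 279 (without its replicate 2) to 1224 (without 5xFAD;CD33-/- replicate 4) against CD33 knockout. With a double knockout library left out, the lone library is assumed to vary like the other groups. The same holds with the title batch as a term, since double knockout replicate 2 was the only library of its title batch. The test of non-additivity gave 0 to 1, with 1 without double knockout replicate 1 and 1 without replicate 2. At 8 months the ranges were 188 (without 5xFAD replicate 5) to 561 (without 5xFAD;CD33-/- replicate 4) for CD33 knockout, 6839 to 7445 for the model, 1794 to 2243 for TREM2 knockout against 5xFAD and 4810 to 5448 against WT.

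Cd33 in the double knockout against CD33 knockout turned from 2.16 to -0.27 without the library labelled double knockout replicate 1 and to -0.31 without the libraries with both Xist and Y-linked reads, which include it. Without replicate 2 it was 4.59. With the endothelial covariate Esam, itself part of that covariate, turned to -0.0632 in CD33 knockout at 8 months. With it App turned to -0.0891 in the model at 8 months and to -0.0822 in TREM2 knockout against WT. Cd33 in TREM2 knockout against WT turned to 0.11 with it. Of the gene lists, 173 passed over the comparisons and 17 with an estimated correlation. The correlation of 4 and 8 months was 0.603 with no filter for CD33 knockout, 0.565 with no filter and 0.779 with the stricter filter for TREM2 knockout, and 0.816 with no filter for the model.

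Another size factor with a count model had been planned for deposited raw counts. The deposited values are RPKM, and no count model was run, although read numbers were recovered; the fit with voom used those.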

Other observations

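The random splits of libraries described here were planned; the splits within title batches and the test of a Y-linked signal were chosen after the values were seen.

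For each comparison with at least 3 libraries per group, the libraries were also split at random into groups of the same sizes, 100 splits per comparison with the real split included. At 4 months the real split of 5xFAD and WT called 2181 genes and the highest other 1259, and 1 of 100 splits called as many, so chance can be excluded. For TREM2 knockout at 4 months the real split called 311 and the highest other 303 (1 of 100). By this small margin chance is excluded only for splits that ignore the title batch. At 8 months chance can be excluded for the model (7428 against 2916, 1 of 100), for TREM2 knockout against 5xFAD (2189 against 1642, 1 of 100) and for TREM2 knockout against WT (5342 against 2132, 1 of 100). For CD33 knockout at 8 months the real split called 374 and the highest other 464, with 2 of 100 as large. That share is under 0.05 but was not adjusted over comparisons. For CD33 knockout at 4 months the real split called 638 and 3 of 100 splits called as many, a share under 0.05 that was not adjusted either. The highest other split called 2660, so these splits do not exclude chance for that count. A split that calls several times the real count points to a structure of the samples other than the genotype; that split put 5xFAD replicates 1 and 8 and 5xFAD;CD33-/- replicates 2 and 3 together.

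Those splits ignored the title batch, so the libraries were also split within title batches only, with the same fit. At 8 months the highest other split called 0 genes for CD33 knockout (374 in the real split, 1 of 100 as large), 1358 for TREM2 knockout against 5xFAD (2189, 1 of 100), 5859 for the model (7428, 1 of 54) and 3433 for TREM2 knockout against WT (5342, 1 of 24). At 4 months it was 1024 for the model (2181, 1 of 64) and 135 for CD33 knockout (638, 1 of 24). Chance can be excluded at a share under 0.05, not adjusted over comparisons, for each of these 6 comparisons. Where 24 splits were possible, 1 of 24 was the smallest share that could arise. For CD33 knockout at 4 months only 3 title batches held both genotypes, and 5xFAD libraries of other batches never moved. Chance is excluded there only for these few exchanges. For TREM2 knockout at 4 months the highest other split called 218 against 311, and the 16 splits within batches are too few for a share under 0.05.

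At 4 months 3 libraries held both Xist, which is transcribed from the inactive X chromosome, and the mean of Y-linked genes above 10% of their highest values in the table. In 5xFAD;CD33-/- replicate 2 Xist was 14.02 RPKM and the Y-linked mean 2.65, in the library labelled double knockout replicate 1 they were 24.4 and 2.78, and in 5xFAD;TREM2-/- replicate 9 they were 19.9 and 2.25. Traces of the other signal were read in further libraries, with Xist up to 0.0316 RPKM beside Y-linked genes and a Y-linked mean up to 0.00439 beside Xist. In the TREM2 table at 8 months, 5xFAD replicate 9 held Ftl2 at 9.65 RPKM, while the other 5xFAD libraries were at 0.163 or lower, and its Cd33 was 59.7, against 80.8 to 116.9 in the others.

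A hypothesis that DAM stage 2 values follow a Y-linked signal within groups was tested with that signal as a covariate. DAM stage 2 genes were lower with more Y-linked signal in 24 of 24 members at 4 months (camera adjusted p = 7.63e-19, adjusted p = 0.0789 with an estimated correlation) and in 21 of 24 in the TREM2 table at 8 months (adjusted p = 3.65e-06, adjusted p = 0.508 with an estimated correlation). A contribution of the Y-linked signal to DAM values may exist, but it cannot be told apart from chance here, because the calls ended with the estimated correlation at both ages. The labels give no sex. Apart from the libraries with both signals, each library held mainly Xist or mainly Y-linked reads, unevenly over the groups. The median Y-linked mean at 4 months was 0.00255 RPKM in WT, 4.90 in 5xFAD, 1.33 in 5xFAD;CD33-/-, 1.13 in 5xFAD;TREM2-/- and 1.39 in the double knockouts. In the CD33 table it was 6.45 in 5xFAD and 0.00326 in the knockout. In the TREM2 table it was 3.28 in WT, 3.17 in 5xFAD and 0.00349 in the knockout.

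The mean of the endothelial list differed between groups within each table. At 4 months it was 3.75 ± 0.362 in WT, 4.47 ± 0.725 in 5xFAD and 5.45 ± 0.695 in 5xFAD;CD33-/- on the log2 scale. In the TREM2 table at 8 months it was 4.82 ± 0.449 in WT, 6.11 ± 0.602 in 5xFAD and 6.43 ± 0.423 in 5xFAD;TREM2-/-.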
